A study of Oryza sativa with 6 samples.

How the data were processed

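Small RNA was sequenced from seedlings of rice (Oryza sativa, indica cultivar Pusa Basmati 1) at 5 weeks of age. The plants were wild type (WT) or carried a transgene meant to over-express (OE) or knock down (KD) OsRDR3, an RNA-dependent RNA polymerase gene, and each group had 2 libraries. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the libraries were made from size-fractionated total RNA extracted with Trizol. The deposited values were raw read counts, 1 for each distinct sequence of 19 to 25 nt, with no header and no normalization by the authors. No sequence was listed more than once in a file, and 0 sequences held a base other than A, C, G or T. Adapter trimming, quality filters, aligner and genome build are not given in the sources used here. Because lengths outside 19 to 25 nt were not in the files, each share below is a share of reads in that range.

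Total counts ran from 7881342 to 25710023 reads per library, over 15124677 distinct sequences in all. Between 76.0% and 82.0% of the distinct sequences of a library were seen once. The 10 most abundant sequences took 14.2% to 16.9% of its reads. The chi-square of counts between the libraries of a group, per degree of freedom, was 6.68 for WT, 9.05 for OE and 4.81 for KD over 10008 sequences with at least 50 reads in every library, so no pair differed by as little as sampling noise, and all 6 libraries were used. Intervals on a share are exact Clopper-Pearson intervals at the 95% level, and a count of 0 was read as a limit of 3 reads. Both cover counting error only, since reads copied in PCR are not independent molecules. The labels do not say that the libraries of a group came from separate plants or lines, so p-values measure only the spread between these libraries, which may be technical.

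No genome was used here, so sequences were not mapped. The planned counts in genome windows, reads on the OsRDR3 locus and on other silencing genes (a list of annotation words for polymerases, Dicer-like, Argonaute and methylation genes), mapped shares of organelle, rRNA and tRNA reads and the mapping alternatives were therefore not run. In their place, reads were compared with sequences. A list of 61 rice miRNA sequences in 10 groups by known target, and the vector parts (a CaMV 35S promoter, a NOS terminator and hygromycin phosphotransferase, a plant selection marker), were fixed before the data were examined. Animal miRNAs (18 arthropod, 9 bilaterian, 9 mammalian, matched over 17 nt at the 5' end), rRNA sequences and a 5' tRNA signature were added after the data were seen. Reads of 21 nt were counted for the TAS3 siRNA known as tasiARF if their first 18 nt matched it, with C or T allowed at 1 base and the last bases free. Sequences at least 20 times more abundant in 1 group than in the pooled other libraries, with at least 2 reads in each library of that group, were joined over exact overlaps of 15 nt, and stretches of 60 nt or more were kept. This assembly was also chosen after the data were seen.

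Sequences of 20 to 24 nt were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with TMM factors, library sizes equal to all reads of the file, and the default count filter with a minimum count of 10. All 6 libraries entered 1 fit with 3 residual degrees of freedom, each pair of groups was a contrast, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The filter kept 80221 sequences, which held 53.0% of all reads. The standard error of a log2 change is its size over the root of the F statistic. The biological coefficient of variation was 11.9%. On simulated data for the OE and WT contrast over 80221 sequences, 14 of 100 sequences changed 2-fold and 73 of 100 changed 4-fold were recovered, and 23 unchanged sequences were called. False calls thus took a larger share of the calls in this simulation than the threshold of 0.05 sets. The counts of called sequences below carry this limit. Groups of miRNAs with at least 2 tested members were tested with fry (limma 3.58.1), 24 tests in 1 family. It asks whether the members moved, on balance, in 1 direction, and does not compare them with other sequences. Shares of reads were compared by exact permutation of 2 against 2 libraries, where the smallest possible two-sided p is 0.33. Distinct sequences were counted after thinning each library to 7881342 reads.

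The named miRNAs are, for each contrast, those past the threshold, at most 15 by smallest p, with the 5 most abundant on the list. Of the unlisted sequences, the 2 with the largest rise and the 2 with the largest fall were named, among those past the threshold, in the upper part of the tested sequences by abundance, and with no overlap between the groups. Sequences of the vector, or with an animal miRNA or its 7-nt seed, were counted but are not printed. The alternatives were DESeq2 1.42.0, RLE factors, library totals, a minimum of 6 reads over all libraries, only the groups compared, replicate number as a block, each library left out, and summed 3' variants sharing 18 nt with a listed miRNA. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.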

Results

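The series asked how small RNAs of rice seedlings differ when OsRDR3 is over-expressed or knocked down. OsRDR3 belongs to the RNA-dependent RNA polymerases, which copy RNA into double strands. Small RNA libraries of 5-week-old seedlings were read to 8379074 and 15885025 reads in WT, 25710023 and 13739997 in OE, and 12115654 and 7881342 in KD.

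Small RNAs do not measure the OsRDR3 transcript, so whether it rose in OE or fell in KD was not observed. Small RNAs of a vector marker separated OE from WT and KD. So did those of stretches assembled from sequences more abundant in OE than in the other groups, where the choice of sequences set the division in advance. In OE, 1 assembled stretch of 524 nt had a reading frame open throughout, with codons for DFDGD, a catalytic motif of 1 class of plant RNA-dependent RNA polymerases, at nt 350 to 364. Reads of this stretch reached 3907 and 3874 RPM (reads per 1000000 reads of the library) in the OE libraries, against 0.119 and 1.70 RPM in WT (1 and 27 reads) and 9.08 and 7.23 RPM in KD (110 and 57 reads). In OE, 73.2% and 73.4% of them were 21 nt long, 16.4% and 16.2% were 22 nt, and 51.0% and 50.9% lay on the coding strand. The most abundant 21-nt sequence over the motif codons, AACAGTGATTTTGACGGTGAC, encoding NSDFDGD, stood at 141 and 138 RPM in OE, at 0 reads in both WT libraries, and at 0.330 and 0.381 RPM in KD. It was picked after the data were seen. Counted without a choice by group, all reads with codons for DFDGD on either strand stood at 322 and 308 RPM in OE. They stood at 1.43 and 1.38 RPM in WT and at 1.16 and 1.52 RPM in KD. Without a genome, OsRDR3 was not told apart from related genes as the source of this stretch.

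Hygromycin phosphotransferase, the selection marker of many rice vectors, gave the same division. Its reads reached 5453 and 5912 RPM in OE, where 77.5% and 77.8% were 21 nt long and 59.3% and 59.2% were sense. In WT the marker stood at 0.597 and 2.90 RPM (5 and 46 reads). In KD it stood at 10.1 and 10.8 RPM (122 and 85 reads), of which 89.3% (95% exact interval 82.5 to 94.2) and 96.5% (90.0 to 99.3) were sense and 34.4% and 31.8% were 21 nt long. In WT replicate 2, 60.9% were sense (45.4 to 74.9). The CaMV 35S promoter and the NOS terminator had at most 1 read in any library, and a count of 0 allows 0.117 to 0.381 RPM. The assembly gave 15 OE stretches with 2664 nt in all, of which 5 were of the marker and 9 others held an open frame, against 1 stretch of 61 nt in KD and 2 in WT. Nothing measured here ties the 9 other stretches to a transgene. Sequences on the 15 stretches or the vector parts, called OE-stretch sequences here, made up 1.69% ± 0.0522 of OE reads and 7.02% ± 0.0339 of OE 21-nt reads (SD, n = 2). Among 499 sequences of 20 to 22 nt restricted to KD, none lay within 3 mismatches of an OE stretch, and the closest had 4. This set took only sequences more abundant in KD than in every other library. Sequences abundant in OE were thus barred in advance, so the result says little about small RNAs of these stretches in KD.

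**Figure D1:**
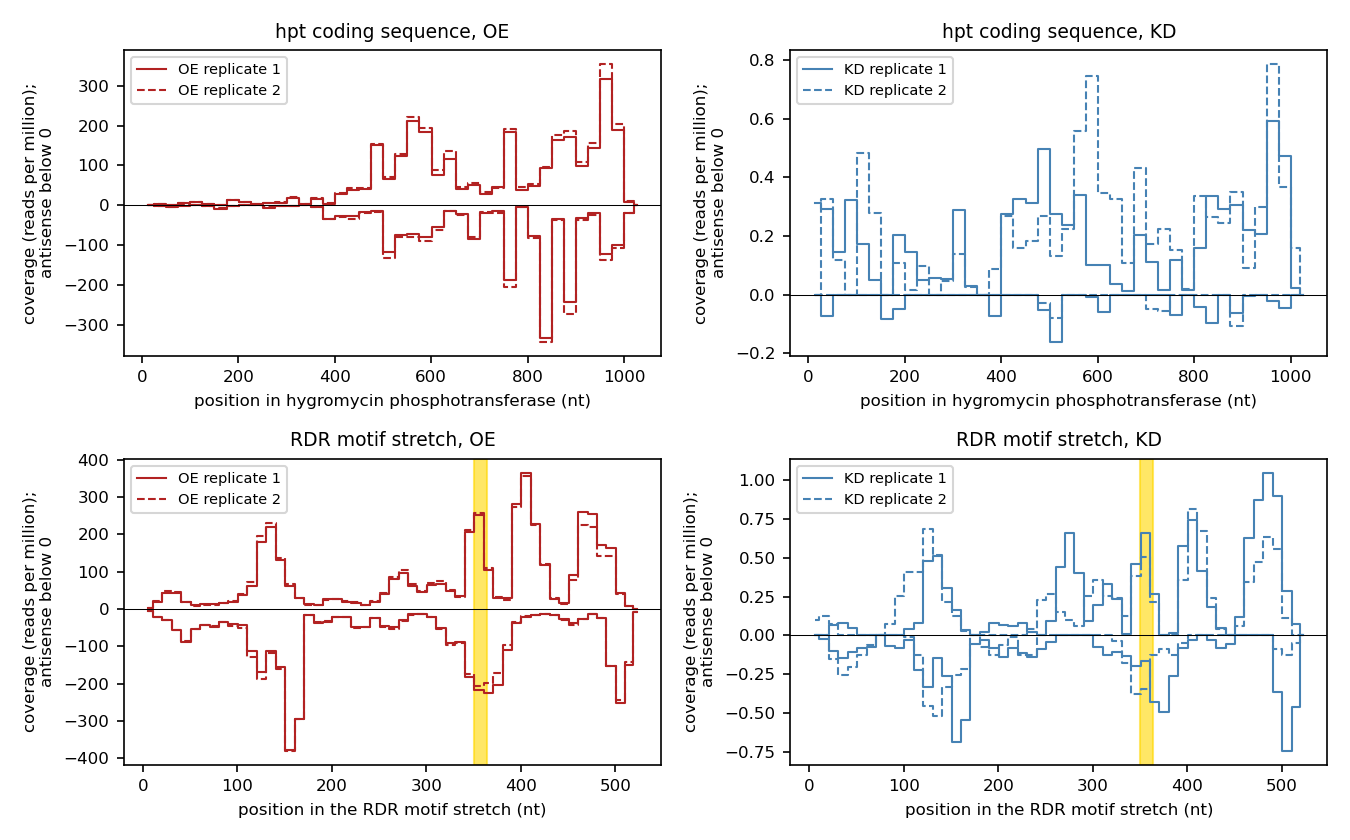
Coverage in RPM along hygromycin phosphotransferase (top, hpt) and the 524-nt RDR motif stretch (bottom) in OE (left) and KD (right), as means over bins, with sense above 0 and antisense below 0 and each replicate as a line. The band marks the DFDGD codons at nt 350 to 364, and the vertical scales of OE and KD differ.

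The 24-nt class, the heterochromatic siRNA size, made up 31.2% ± 0.720 of reads in WT, 34.6% ± 0.763 in OE and 27.4% ± 0.920 in KD (SD, n = 2), with no overlap between the groups' libraries. Of distinct sequences at equal depth, 24-nt ones were 50.8% ± 0.410 in WT, 52.9% ± 0.369 in OE and 48.1% ± 0.667 in KD. The 21-nt class, the usual size of miRNAs, was 16.96% ± 0.547 in WT, 17.8% ± 0.524 in OE and 16.2% ± 0.488 in KD. Without OE-stretch sequences the OE minus WT difference of the 21-nt class went from 0.888 to −0.079 percentage points. These sequences were chosen for being higher in OE, so a drop was set in advance and does not show what caused the difference. With all sequences the difference was 0.502 without WT replicate 1 and 0.518 without OE replicate 2. The 22-nt class was 14.4% ± 0.392, 14.1% ± 0.252 and 14.5% ± 0.149 in WT, OE and KD. The OE and KD libraries each overlapped those of WT, and all KD libraries were above those of OE, by 0.336 percentage points in the means (0.514 without OE replicate 1 and 0.157 without OE replicate 2). Over reads of 20 to 24 nt the 22-nt differences were −0.692 percentage points for OE minus WT and 0.761 for KD minus WT. Each of these comparisons is 2 against 2 libraries, where an exact permutation test gives at least p = 0.33.

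The 19-nt share and the 5' tRNA signature were lower in OE and higher in KD than in WT, an order that the rRNA fragments did not follow. The 19-nt share was 7.63% ± 0.497 in WT, 6.24% ± 0.347 in OE and 10.04% ± 0.577 in KD (SD, n = 2). Reads with the 5' tRNA signature made up 2.18% ± 0.155 in WT, 1.35% ± 0.0763 in OE and 3.59% ± 0.268 in KD. Chloroplast rRNA fragments made up 0.817% ± 0.0518, 0.449% ± 0.0234 and 0.771% ± 0.0449, and cytosolic rRNA fragments 2.06% ± 0.177, 2.12% ± 0.0695 and 2.53% ± 0.128, where KD overlapped WT in the first and OE overlapped WT in the second. Without rRNA and tRNA fragments, the KD minus WT difference of the 24-nt share was −3.29 percentage points. The 19-nt share was then 6.39% and 6.91% in the WT libraries, 5.32% and 5.69% in OE and 7.28% and 7.77% in KD. The groups kept their order but lay closer together than with all reads.

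**Figure D2:**
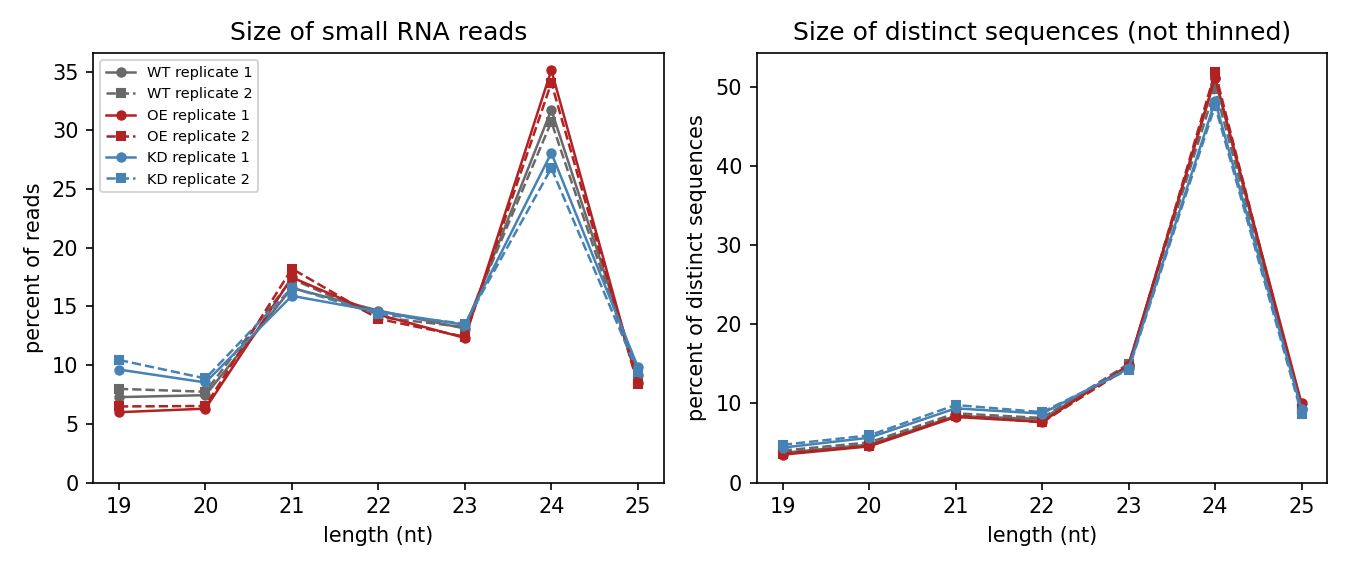
Percent of reads (left) and of distinct sequences (right) by length in nt, 1 line per library, with WT in grey, OE in red and KD in blue. At 24 nt the OE libraries lie between 34.1% and 35.1% of reads, the WT libraries between 30.7% and 31.8% and the KD libraries between 26.8% and 28.1%.

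The OE and WT comparison asked what changed with the over-expression transgene. Members of the miR166 family, which target HD-ZIP III leaf polarity genes, and miR396c, of a family that targets growth-regulating factors, rose. The most abundant miRNA on the list, miR166a-d,f, went from 11327 ± 1246 RPM in WT to 23864 ± 2338 in OE (SD, n = 2), a log2 change of 1.15 (SE 0.115), and miR396c from 304 ± 13.7 to 661 ± 2.90, a log2 change of 1.19 (SE 0.113). The flowering-time and phase-change miR156a-j, which targets SPL genes, fell from 350 ± 3.48 to 186 ± 5.91 RPM, a log2 change of −0.84 (SE 0.114). In auxin signalling, miR167a-c fell to 11.7 ± 2.43 RPM from 28.9 ± 0.485, a log2 change of −1.25 (SE 0.155), whereas miR167d-j, of the same family, rose by 0.72 (SE 0.119).

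By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all sequences, 24 of 45 tested miRNAs changed, 10 higher and 14 lower in OE. Adjusted over the list alone the count was 26, with 12 higher and 14 lower. In the auxin group, 4 of 6 members fell (miR160a-d by 0.87 on the log2 scale, miR160e by 1.03, miR167a-c and miR393a) and 1 rose, and fry called the group lower (adjusted p = 0.0265). In the developmental timing group, miR156a-j and miR535 fell, none of 4 rose, and fry called it lower (adjusted p = 0.0208). In the meristem and leaf group, 4 of 15 rose, namely miR166a-d,f, miR166k,l (0.93), miR166g,h (0.80) and miR396c, and 3 fell, namely miR394 (−0.99), miR171b-f (−0.62) and miR396e (−0.40), and fry made no call in 1 direction (adjusted p = 0.143). Of 8 stress miRNAs, 5 fell, among them miR1425 (3522 ± 281 to 1937 ± 96.3 RPM, −0.79), miR169b,c (−0.88), miR169n,o (−1.14), and miR169f,g (−1.15), and 2 rose, miR1432 (0.90) and miR1318 (0.68), with no call by fry (adjusted p = 0.0639). In the copper group 1 of 4 rose, miR398b, in the silencing feedback group 1 of 3, miR162a, and in the phosphate and monocot MADS groups no tested member passed. Adjusted over the list alone, 2 of 3 silencing feedback members rose, miR162a and miR168a. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all sequences, miR396c had the smallest adjusted p, 2.77e-08. By the same test and adjustment miR168a, which targets AGO1, missed the threshold at 9351 ± 380 RPM in WT and 10880.5 ± 498 in OE (adjusted p = 0.0545). Without WT replicate 2, miR168a passed it (adjusted p = 0.0130 by edgeR, Benjamini-Hochberg). Both fry calls were lost when any 1 library was left out, with adjusted p of 0.0581 to 0.129, and with 3' variants summed the changes of miR167a-c and miR167d-j, which share their first 18 nt, were both −0.01 and neither was called, and that of miR396e was −0.28 and not called.

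Of all tested sequences, 21339 of 80221 differed between OE and WT by edgeR's quasi-likelihood test, 10478 higher and 10861 lower. The balance turned to more higher with the looser count filter, 6977 higher and 4936 lower, and without WT replicate 2, 6844 and 5905, and it was 7640 higher and 11116 lower without OE-stretch and animal-matching sequences. Among 24-nt sequences 6122 rose and 2656 fell, whereas among 20-nt sequences 392 rose and 1869 fell. The 2016 OE-stretch sequences tested were higher in OE, but the stretches had been assembled from sequences chosen for being higher in OE. Of 1312 rRNA or tRNA fragments 64 rose and 436 fell. The 24-nt ATCATGTCAATAGTAAATCACTGT was at 10.4 ± 1.69 RPM in WT, 0 reads in OE and 0.730 ± 0.135 in KD, at least 137-fold lower in OE against a limit of 3 reads over the group, and ATTAGAACCTATCATCGTTGTGAT was at 8.25 ± 1.16 RPM in WT and 0 reads in OE, at least 108-fold lower. The largest rises were of OE-stretch 21-nt sequences, at least 1540-fold and 1146-fold. The count of sequences was 12749 without WT replicate 2, 12808 without OE replicate 1, 8211 with DESeq2 and 11913 with the looser count filter, under which 6 miRNAs were called.

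The KD and WT comparison asked what changed with the knock-down transgene. Of the copper-responsive miRNAs, 3 of 4 tested were higher in KD (miR397a was not, at −0.09), and both tested phosphate-responsive ones were lower. The copper group's miR398b, which targets superoxide dismutase genes, went from 15.8 ± 1.25 RPM in WT to 60.5 ± 7.08 in KD (SD, n = 2), a log2 change of 1.96 (SE 0.160), and miR408-3p from 8.50 ± 0.538 to 19.6 ± 3.12, a log2 change of 1.22. The phosphate starvation miRNAs miR399d and miR827 fell from 4.04 ± 0.194 to 0.752 ± 0.0130 RPM (log2 change −2.37, SE 0.329) and from 80.3 ± 4.55 to 26.5 ± 3.12 RPM (−1.57, SE 0.138). Outside these groups miR1318 rose from 15.7 ± 3.19 to 63.0 ± 4.17 RPM (2.02, SE 0.153) and miR1432 from 81.7 ± 0.448 to 285 ± 18.2 RPM (1.84, SE 0.122).

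By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all sequences, 24 of 45 tested miRNAs changed, 8 higher and 16 lower in KD, and adjusted over the list alone 28 did, 9 higher and 19 lower. In the copper group 3 of 4 rose (miR528 by 1.14 as well) and none fell, and fry called it higher (adjusted p = 0.0406). Both tested members of the phosphate and sulphate group fell (fry, adjusted p = 0.0108). In the auxin group 4 of 6 fell, namely miR160a-d (−0.81), miR160e (−0.59), miR167a-c (−0.68) and miR393a (−0.72), and none rose (fry, adjusted p = 0.0256), but with 3' variants summed miR167d-j, at 0.0074 alone, went with miR167a-c to −1.26 and was called. In the meristem and leaf group 4 of 15 fell and none rose, with miR164a,b,f, which targets NAC genes, going from 23.7 ± 2.41 to 7.997 ± 0.363 RPM (−1.53) and miR396e from 6575 ± 162 to 3873 ± 103 RPM (−0.73), and fry made no call (adjusted p = 0.0639). In developmental timing, miR529b rose (1.61, but 0.12 and not called with 3' variants summed) while miR172a,d (−0.93) and miR535 (−0.61) fell, and fry's direction was down with a median of −0.14 and a mean of 0.10 (adjusted p = 0.322). Among 8 stress miRNAs, miR1432, miR1318 and miR169a (0.82) rose, and miR1425 (−0.82), miR169n,o (−1.47) and miR169h-m (−0.52, but −0.28 and not called with 3' variants summed) fell, with fry's direction up, a median of −0.13 and a mean of 0.20 (adjusted p = 0.0705). Of the monocot MADS pair, miR444b.2 fell (−0.52). The TAS3 trigger miR390 rose from 47.1 ± 5.90 to 89.3 ± 0.574 RPM (0.95). Its product tasiARF stood at 1.05 ± 0.300 RPM in WT, 0.50 ± 0.322 in OE and 0.565 ± 0.0984 in KD. Both WT libraries were above those of OE and KD (exact permutation test, p = 0.33, the smallest possible), but these are few reads. WT replicate 1 held 0.835 RPM and OE replicate 2 0.728 RPM, where a count of 0 allows 0.358 and 0.218 RPM. A fall of tasiARF was thus not established. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, miR1432 had the smallest adjusted p, 4.86e-10, while miR166a-d,f, miR168a and miR159a,b had log2 changes of −0.05, −0.24 and 0.09 and did not pass. The 3 fry calls were lost when any 1 library was left out, with adjusted p of 0.0581 to 0.151. The reproductive phasiRNA triggers miR2118a and miR2275a had 0 reads in all libraries.

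Of the tested sequences, 9216 differed between KD and WT by edgeR's quasi-likelihood test, 5669 higher and 3547 lower. At 24 nt 1382 sequences were higher and 2118 lower, and at 22 nt 1170 were higher and 300 lower, where in OE 936 were higher, of which 492 were not OE-stretch sequences, and 2058 lower. At 21 nt 1259 were higher and 500 lower in KD, and in OE 2301 were higher, of which 1009 were not OE-stretch sequences, and 2208 lower. Of rRNA or tRNA fragments, 149 rose and 63 fell. The 24-nt AATCAGGACCCACTATATCAGGAG was at 31.3 ± 2.35 RPM in WT, 36.5 ± 2.17 in OE and 0 reads in KD, at least 208-fold lower in KD, and the 21-nt TTCGCATCCACTGTGTGACCC was at 16.9 ± 3.93 RPM in WT, 4.01 ± 1.33 in OE and 0 reads in KD, at least 112-fold lower. The largest rises, at least 117-fold and 116-fold, were of sequences with an animal miRNA seed. The count was 5947 without WT replicate 2, 5025 without KD replicate 1, 2901 with DESeq2 and 3177 with the looser count filter, under which 10 miRNAs were called.

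**Figure D3:**
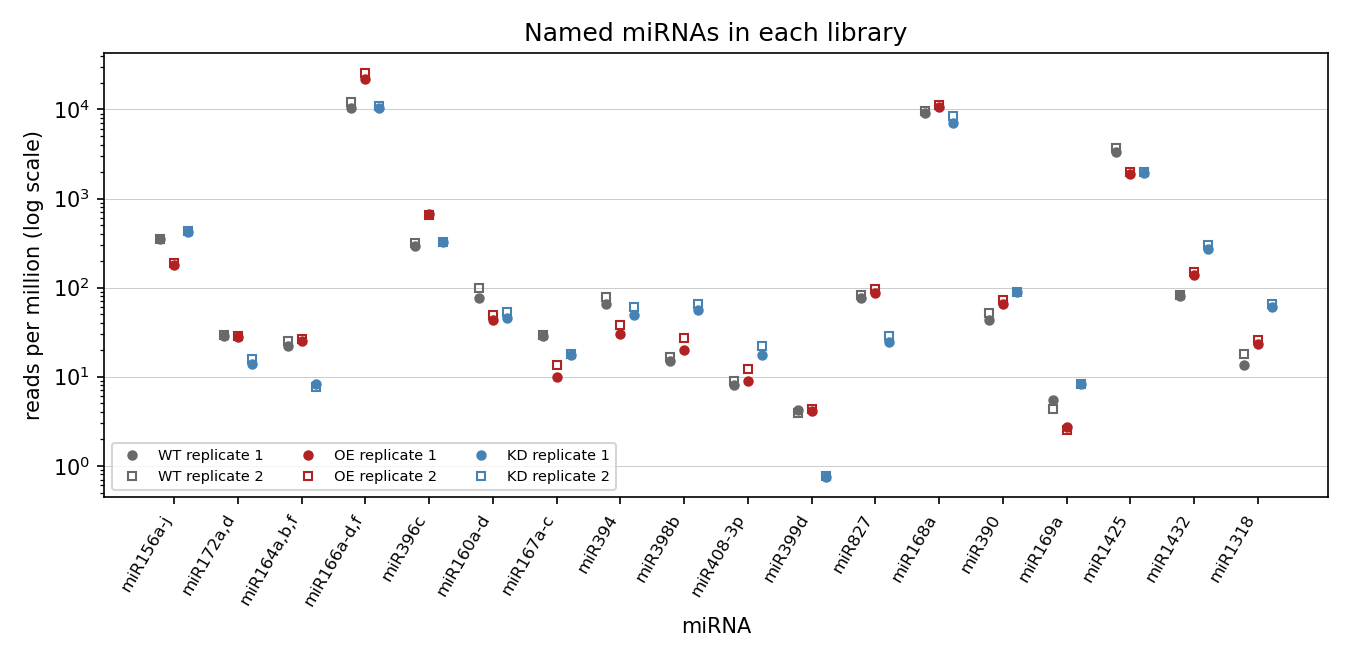
Abundance of 18 miRNAs in RPM on a log scale, with each library as a point (circles, replicate 1, and open squares, replicate 2). The KD libraries stand apart for miR398b, at a mean of 60.5 RPM, and for miR827, at 26.5 RPM, and the OE libraries for miR396c, at 661 RPM.

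The OE and KD comparison set the transgenic groups against each other. Both tested phosphate miRNAs were higher in OE than in KD, with miR827 at 91.6 ± 7.49 against 26.5 ± 3.12 RPM (log2 change 1.83, SE 0.138) and miR399d at 4.23 ± 0.20 against 0.752 ± 0.0130 RPM (2.51, SE 0.312). Leaf and meristem miRNAs were mostly higher in OE, among them miR164a,b,f (1.73), miR166a-d,f (1.195) and miR396c (1.07). The silencing feedback miRNAs miR162a (0.74), which targets DCL1, and miR168a (0.53) were also higher in OE. Lower in OE were miR156a-j (−1.17, SE 0.114), miR398b (−1.34), miR1318 (−1.33), miR169a (−1.61) and miR529b (−2.03, but −0.14 and not called with 3' variants summed).

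By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all sequences, 31 of 45 tested miRNAs differed, 17 higher and 14 lower in OE, and adjusted over the list alone 33 did, 18 higher and 15 lower. With 3' variants summed 24 were higher and 11 lower. Members that share their first 18 nt, such as miR393a and miR393b, then had the same sum, counted under each name. The balance of that count is thus not comparable with the one above. With the looser count filter the balance turned, 6 higher and 8 lower. In the meristem and leaf group 10 of 15 were higher in OE, miR166g,h (1.07), miR166k,l (0.97) and miR166m (1.24) among them, and 1 was lower, miR394 (−0.64) (fry, adjusted p = 0.0263). Both phosphate and sulphate members were higher (fry, adjusted p = 0.00961), as were 2 of 3 silencing feedback members (fry, adjusted p = 0.0450, or 0.0634 and no call with RLE factors). In developmental timing, miR156a-j and miR529b were lower and miR172a,d was higher (0.96), with fry calling the group lower (adjusted p = 0.0234, or 0.137 and no call with 3' variants summed). Of 8 stress miRNAs 5 were lower, including miR1432 (−0.94), miR169b,c (−1.12) and miR169f,g (−0.65, but −0.12 and not called with 3' variants summed), and none was higher (fry, adjusted p = 0.0234). In the copper group 3 of 4 were lower, with no call by fry (adjusted p = 0.0601), and the auxin group had 1 member higher and 2 lower (fry, adjusted p = 0.426), and with 3' variants summed miR167a-c (−0.57) turned to 1.25, miR160e (−0.44) was −0.17 and not called, and fry called the group higher (adjusted p = 0.0204). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, miR827 had the smallest adjusted p, 4.21e-10. The 5 fry calls were lost when any 1 library was left out, with adjusted p of 0.0571 to 0.251. Without KD replicate 1, miR168a missed the threshold (adjusted p = 0.0539 by edgeR, Benjamini-Hochberg), and miR396e, at 0.32 with all libraries, missed it without any 1 of the OE or KD libraries (adjusted p of 0.0596 to 0.237 by edgeR, Benjamini-Hochberg) and with DESeq2. Of all sequences, 32253 differed by edgeR's quasi-likelihood test, 14862 higher and 17391 lower in OE, and of the 24-nt ones 10342 were higher and 3722 lower. The count was 20948 without OE replicate 1, 13421 with DESeq2 and 17681 with the looser count filter, under which 14 miRNAs were called. The largest differences were of OE-stretch sequences, at least 945-fold and 918-fold higher in OE, and of sequences with an animal miRNA seed, at least 190-fold and 137-fold lower.

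Over-expression and knock-down of a gene raise the question whether small RNAs move in opposite directions. Of the miRNAs, miR398b, miR390, miR1432 and miR1318 were higher than WT in both OE and KD, against 1.78 for independent lists. Of these, miR1318 is the sequence of miR1432 without its first base, so they are not separate members. The 8 that were lower in both, against 4.98, were miR535, miR396e, miR160a-d, miR160e, miR167a-c, miR393a, miR169n,o and miR1425. The OE and KD lists share the WT libraries, so the values for independent lists are not those that unchanged groups would give. Adjusted over all sequences, miR169a moved apart, lower in OE and higher in KD, against 2.49, and 0 were higher in OE and lower in KD, against 3.56. Adjusted over the list alone, miR156a-j and miR169a were lower in OE and higher in KD, against 2.8, and miR162a and miR166m were higher in OE and lower in KD, against 5.07, while the 4 higher in both stayed and miR394 joined those lower in both, 9 against 5.91. With 3' variants summed, the OE changes of miR167a-c and miR396e were not called, nor was the KD change of miR166m. Calls were gained as well. The KD rise of miR156a-j was then called (0.36), opposite to its fall in OE, and miR166m was called higher in OE (1.12). On the other side, miR393b, which has the same sum as miR393a, was called lower in OE (−0.36) and in KD (−0.69). Over all tested sequences, 1241 were higher in both (740 for independent lists, 1 in simulated unchanged groups sharing the WT libraries), and 1122 lower in both (480 and 1.2). The counts were 197 for higher in OE and lower in KD (463 and 0), and 480 for lower in OE and higher in KD (768 and 0). The simulated groups held no change and gave few calls, so their overlap counts were near 0 in advance. Those counts do not measure an excess of overlap. The log2 changes had a correlation of 0.186 across sequences, which are not independent replicates, against 0.517 in the simulated groups, and a covariance of 0.315 against 0.0964, a difference of 0.218. When OE and KD were each compared with a different WT library, in both ways, 460 and 429 were higher in both (259 and 279 for independent lists) and 554 and 487 lower in both (171 and 179), with covariances of 0.223 and 0.202 against 0.00056 and 0.00108 in the simulated groups. The lone WT libraries were then assumed to vary like OE and KD. This comparison was chosen after the data were seen. By length, the median log2 changes from WT of all tested sequences had opposite signs in OE and KD. They were 0.304 in OE and −0.191 in KD at 24 nt, −0.196 and 0.120 at 23 nt, and −0.316 and 0.216 at 22 nt. At 21 nt they were −0.099 and 0.104, and at 20 nt −0.416 and 0.205.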

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

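All tests in this part were chosen after the result was seen. Of the sequences tested above, 44 were classed as matching an animal miRNA, of which 17 were higher and 17 lower in KD than in WT, and 3 and 11 in OE. Reads matching 18 arthropod miRNAs stood above both WT libraries in both transgenic groups. They reached a mean of 119.6 RPM in KD (105 and 134) and 12.9 RPM in OE (11.5 and 14.3), against 4.77 and 4.91 RPM in WT. In OE, much of this was miR-276, at 7.39 and 5.82 RPM against 2.63 and 2.20 in WT, a member that in KD stood at 3.38 and 18.1, and the source of the OE reads was not tested. In KD, 5 list members (bantam, miR-8, miR-184, miR-317 and miR-12) were above 5 times every other library in both libraries with 20 or more reads in each, as arthropod RNA that entered both KD samples or libraries from outside the series would give. Among the distinct sequences of all libraries, 0.0158 were expected to match by chance, while 156 matched, so chance is excluded. Reads of the WT or OE libraries assigned to KD are excluded as well, since the lowest KD library held 7.31 times the highest other library. Whether the arthropod RNA may have come from animals on the plants, from reagents or from other sequencing runs stays open, and no biological explanation through OsRDR3 was tested. Reads matching mammalian miRNAs were at 1080 and 36.7 RPM in WT, 194 and 12.6 in OE and 9.82 and 59.5 in KD, and those shared among bilaterian animals at 58.8 and 3.02, 12.8 and 5.17, and 12.5 and 28.7 RPM.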

How the results depend on the processing

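The alternatives that left out OE-stretch, animal-matching, rRNA or tRNA sequences, and the refits of miRNA groups other than with 3' variants, were chosen after the data were seen. DESeq2 called 8211 sequences for OE and WT, 2901 for KD and WT (48214 adjusted p were NA) and 13421 for OE and KD. With 6 or more reads as the only filter, where more sequences were tested, the counts were 11913, 3177 and 17681, and the miRNA counts 6, 10 and 14. With 1 library left out, sequences ranged from 12749 (without WT replicate 2; 12808 without OE replicate 1) to 24478 for OE and WT, from 5025 (without KD replicate 1; 5947 without WT replicate 2) to 10381 for KD and WT, and from 20948 (without OE replicate 1) to 36074 for OE and KD. A lone library was then assumed to vary like the other groups. RLE factors, library totals, fits of only the compared groups and fits without OE-stretch and animal-matching sequences (18756, 9160 and 29713) kept the counts within 1.5 times. The balance of OE and WT changes turned with the 6-read filter, 6977 higher and 4936 lower, and without WT replicate 2, 6844 and 5905.

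Replicate numbers do not pair the libraries by their labels. Same-numbered deviations correlated at 0.515 for OE and WT, 0.487 for KD and WT and 0.445 for OE and KD, and the log2 ratio of replicate 1 to 2 correlated with GC content at −0.390, −0.367 and −0.401 in WT, OE and KD. With the replicate number as a block, 24918, 13154 and 36493 sequences were called, of which 20927, 9128 and 32034 were shared with the fit without it, and 30, 30 and 35 miRNAs. The block gave a call for miR168a in OE and WT (0.29) and in KD and WT (−0.245), and for miR159a,b in OE and KD (−0.125). None of these was called without it when adjusted over all sequences. The block also brought fry calls for KD and WT in meristem and leaf (adjusted p = 0.0238), monocot MADS (0.0449) and stress (0.00759), for OE and KD in copper (0.0182), and for OE and WT in meristem and leaf (0.0286), phosphate and sulphate (0.0451) and stress (0.00759).

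Other fry results moved as follows, and the cause was not tested. Summed 3' variants gave calls for KD and WT in meristem and leaf (0.0323), for OE and KD in auxin (0.0204) and copper (0.0340) and for OE and WT in silencing feedback (0.0435), and ended that of developmental timing for OE and KD (0.137). Library totals gave 0.0482 for meristem and leaf in KD and WT, for copper in OE and KD and for stress in OE and WT, and RLE factors ended that of silencing feedback in OE and KD (0.0634). With 1 library left out, which leaves fewer samples, every fry call ended. The adjusted p ranged for KD and WT from 0.0694 to 0.151 in auxin, 0.0674 to 0.145 in copper and 0.0581 to 0.0892 in phosphate and sulphate. For OE and KD it ranged from 0.0694 to 0.129 in developmental timing and in stress, 0.0813 to 0.219 in meristem and leaf, 0.0571 to 0.0892 in phosphate and sulphate and 0.108 to 0.251 in silencing feedback. For OE and WT it ranged from 0.0694 to 0.129 in auxin and 0.0581 to 0.129 in developmental timing. Directions of groups without a call turned for developmental timing in KD and WT (0.184 to 0.950, turned without KD replicate 2), auxin in OE and KD (0.322 to 0.939) and monocot MADS in OE and WT (0.141 to 0.810).

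Over reads of 20 to 24 nt the 21-nt difference was −0.117 percentage points for KD and WT and 0.682 for OE and KD, and that of 22 nt −0.692 for OE and WT, 0.761 for KD and WT and −1.45 for OE and KD. Without OE-stretch sequences, which were chosen for being higher in OE, the 21-nt difference was −0.079 for OE and WT and 0.6315 for OE and KD. Without rRNA and tRNA fragments that of 22 nt was −0.726 for OE and KD. Without thinning, the 24-nt share of distinct sequences differed by 1.09 for OE and WT and by 3.59 for OE and KD. The covariance of the OE and KD changes above the simulated value was 0.165 without OE-stretch sequences, and 0.223 and 0.201 with a different WT library for each of OE and KD, which was also chosen after the data were seen.

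Of 59 pairs of a named sequence and a contrast, 27 had the same verdict under every setting. Over 354 tests with 1 library left out, 340 gave the same verdict, 5 were weaker, 1 was stronger and 8 changed sign, and with the 6-read filter 23 pairs were weaker. Summed 3' variants gave −0.012 for both miR167d-j and miR167a-c in OE and WT, which ended calls of 0.72 and −1.25 and turned the first, and ended those of miR529b in KD and WT (0.12) and in OE and KD (−0.145) and of miR396e in OE and WT (−0.28). DESeq2 ended that of miR396e in OE and KD (0.30). The other sign changes were of log2 changes near 0, namely miR1425 for OE and KD with library totals (−0.0078) and with 1 library left out (−0.059 to 0.067), miR159a,b for OE and WT with the 6-read filter (0.0073) and 1 library left out (−0.15 to 0.072), and miR166a-d,f for KD and WT with 1 library left out (−0.17 to 0.12). Changes of scaling shifted the median of all sequences by less than 0.1 on the log2 scale. Not run, since no genome was used here, were the genome windows, the mapped denominator and the mapping alternatives.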

Other observations

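All tests of explanations in this part were chosen after the result was seen. The listed miRNAs together took 3.54% of reads in WT (3.39% and 3.70% in the libraries), 4.66% in OE (4.45% and 4.88%) and 2.89% in KD (2.77% and 3.01%). The total had the same order as the 24-nt share. Of its members, miR166a-d,f alone stood at 11327 RPM in WT, 23864 in OE and 10698 in KD. Its rise in OE was larger than that of the whole list. The other listed miRNAs together were thus not higher in OE than in WT, and the OE end of the order was not theirs. In KD, miR166a-d,f fell from WT by less than the whole list did. The other listed miRNAs together were thus lower in KD than in WT. Of 21-nt reads, 49.3% ± 0.257 began with T in WT, 56.0% ± 0.730 in OE and 43.6% ± 0.288 in KD (SD, n = 2). These include the reads of miR166a-d,f, which is 21 nt long and begins with T. Of 24-nt reads, 48.2% ± 0.195 began with A in WT, 48.5% ± 0.213 in OE and 46.4% ± 0.400 in KD. Some other first-base shares had the same order, such as C in 22-nt reads. It stood at 50.5% and 48.3% in the WT libraries, 53.8% and 51.8% in OE and 46.0% and 44.2% in KD. Shares of T in 22-nt and 24-nt reads did not follow this order. Of 22-nt reads, 22.5% began with T in WT, 19.8% in OE and 20.3% in KD, and for T in 24-nt reads the groups overlapped.

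In OE, hygromycin phosphotransferase and a stretch with an RNA-dependent RNA polymerase motif yielded 3874 RPM or more of small RNAs in each library. Fragments of the transgene mRNA are excluded as the whole source, since 49.1% of reads of the motif stretch were antisense. Assignment of reads from WT or KD libraries is excluded for the marker, as the lowest OE library held 506 times the highest other library. The motif stretch was assembled from sequences chosen for being higher in OE, so all reads with codons for DFDGD on either strand were counted without that choice. They stood at 322 and 308 RPM in OE, 1.43 and 1.38 in WT and 1.16 and 1.52 in KD, 202 times higher in the lowest OE library than in the highest other library, which excludes that assignment for the motif part as well. A candidate explanation is double-stranded RNA of the transgene processed to 21 nt in the OE plants, which needs most reads at 21 nt, and the lowest share over both sequences and both libraries was 73.2%. This is a hypothesis found and tested on the same data, and whether it lowers or raises the OsRDR3 transcript was not measured.

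The 24-nt share was higher in OE and lower in KD than in WT. The rRNA and tRNA fragments matched here are excluded as the whole cause, because without them KD still differed from WT by −3.29 percentage points. Depth is excluded for distinct sequences, where at equal depth the difference was −2.73 percentage points. Whether fragments of other longer RNAs may account for part of it stays open. Without the matched fragments, the 19-nt share of KD lay 0.552 percentage points above what the 24-nt change alone gives, or 1.55 pooled SDs, and that of OE lay 2.58 pooled SDs below, so KD fell short of the 2 pooled SDs that this explanation was asked to show. A change in 24-nt siRNA production through OsRDR3 stays open and untested, as no genome was used here to assign the reads to loci.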
